A study of Mus musculus with 19 samples.

How the data were processed

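RNA was measured in whole kidneys of mice in 19 libraries. These were 7 of vehicle-treated obstructed, 8 of zalfermin-treated obstructed and 4 of healthy kidneys. Groups were taken from the sample labels and named after the series design. Per the submitters' processing notes, RNA was extracted with NucleoSpin kits, libraries were made with NEBNext Ultra II Directional chemistry and sequenced on a NextSeq, and reads were aligned to GRCm38 with STAR 2.7.0f. The values used are raw read counts per gene as deposited by the authors, whole numbers with no normalization. The counting program, its strand setting, the annotation and any filter are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be kept apart with certainty. All 55536 gene identifiers are found in GENCODE M21, built on GRCm38, which gave the coordinates. Where several genes carried the same symbol, the one with most reads kept it, and the further genes (118) had their identifier added.

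Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16026 genes; 39510 were not tested, of which 24313 had no count, and these held 0.115% of the counts. Library factors were TMM, 0.751 to 0.843 in healthy, 1.02 to 1.11 in vehicle and 1.02 to 1.08 in zalfermin libraries. A single quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) was fitted to the 19 libraries, and the comparisons were tested with its two-sided F test; adjusted p is Benjamini-Hochberg over all tested genes, with 0.05 as the threshold for a gene being called. No paired analysis was possible because replicate numbers follow only the order of the samples. The 35 gene lists, the sentinel genes, the comparisons and the alternative settings were fixed before the data were examined. Lists with at least 4 tested members (33) were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the lists. The other 2 had no list test: of 2 adrenal cortex genes 1 was called higher with obstruction, and of 3 skeletal muscle genes 1 was called higher and 1 lower, while edgeR, DESeq2 and voom called 0 of them under zalfermin, with 0 at unadjusted p under 0.05. Fgf21 and Klb, with too few reads, were compared by two-sided exact permutation tests of mean CPM.

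Genes were named by a fixed rule. It took the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM and a gene symbol other than a provisional one (such as Gm with a number), provided that the groups did not overlap (obstruction) or that at least 6 of 8 zalfermin libraries lay beyond the vehicle median. It also took 13 sentinel genes (Col1a1, Col3a1, Fn1, Acta2, Tgfb1, Havcr1, Lcn2, Adgre1, Lrp2, Umod, Klb, Fgfr1 and Fgf21) and, for each list, the 2 members with the smallest p and the smallest-p called member against the majority. For genes called in both comparisons it took 5 with opposite and 5 with equal signs. Some genes that the rule took are not reported here.

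The alternative settings fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, voom with quality weights, no filter, a filter of 1 CPM in 10 libraries, a fit of only the 2 groups compared, a robust fit, each library left out in turn, camera with an estimated correlation, fry in place of camera, and the vehicle libraries split between the comparisons. Corrections for GC content and transcript length and 8 further gene lists were chosen after seeing the data.

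The tests were checked on simulated data with the group sizes of this design. Only 67, 67 and 66 genes were changed, 1.5-, 2- and 4-fold, and genes varied independently around 1 common mean. With obstruction 10387 of 16026 genes were called, and real libraries can share deviations. The rates below, and the order of the tools, may therefore not carry over to the real comparisons. For 7 against 4 libraries edgeR recovered 47.8% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, with 2.52% false calls. For 8 against 7 it recovered 76.1%, 94.0% and 100%, with 4.76% false calls, against 18.9% for DESeq2 and 5.32% for voom. Raw sequence reads were not used here.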

Results

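Gene expression was measured by RNA sequencing in whole mouse kidney, in 19 libraries of 3 groups. The series design names 7 libraries of obstructed kidneys given vehicle, 8 of obstructed kidneys given zalfermin and 4 of healthy kidneys. UUO, the abbreviation used there, commonly stands for unilateral ureteral obstruction, a surgical model of kidney fibrosis in mice, and the series title describes zalfermin as a long-acting analogue of FGF21, a metabolic hormone. The sample labels give the condition of the 15 obstructed libraries as MASH, where the series design gives UUO, and they call the healthy libraries untreated, where the design calls them vehicle. The labels give the drug treatment only as a code, taken here to be the zalfermin of the design. The groups themselves are the same in both sources. Dose, duration and time of tissue collection were not given in the sources used here. Libraries held 12209122 to 14844103 counts, and 16026 of 55536 genes had enough counts to be tested. All levels below are CPM, the count as a share of the library's TMM-scaled total, as mean ± SD over 4 healthy, 7 vehicle and 8 zalfermin libraries.

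Healthy and obstructed kidneys separated on the first principal component, which held 66.4% of the variance, while the second, with 8.41%, set vehicle replicate 6 apart. That library had 19788 genes detected against 21374 to 22216 in the other vehicle libraries, and 1.10% of its counts came from mitochondrially encoded genes. The mean mitochondrially encoded share was 9.56% ± 0.608 in healthy, 3.20% ± 0.999 in vehicle and 3.56% ± 0.466 in zalfermin kidneys (SD, n = 4, 7 and 8). Spp1, which encodes osteopontin, took 0.104% ± 0.0117, 2.31% ± 0.519 and 2.76% ± 0.431 of the counts in the same groups. All 19 libraries had more counts of the Y-linked Ddx3y than of Xist, and no pair of libraries in a group was as close as sampling noise alone would make it (chi-square per degree of freedom at least 5.89). The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

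**Figure D1:**
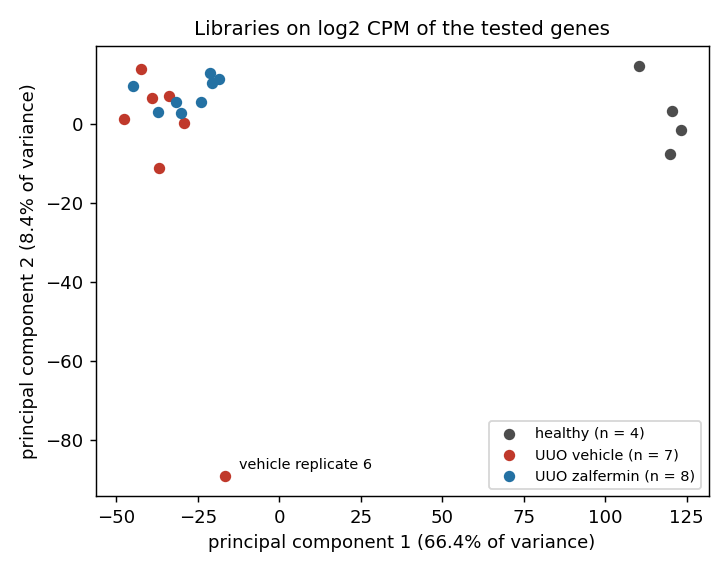
Each point is a library, placed by the first 2 principal components of log2 CPM over the tested genes and coloured by group. Component 1 (66.4% of variance) separates the 4 healthy from the 15 obstructed libraries, and vehicle replicate 6 lies apart on component 2.

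The first comparison, vehicle-treated obstructed against healthy kidneys, asked what obstruction changed. Genes of the extracellular matrix rose. Col1a1, which encodes a chain of type I collagen, rose from 24.0 ± 2.67 CPM in healthy to 746 ± 238 CPM in obstructed kidneys, Col3a1 rose from 37.6 ± 7.75 to 1178 ± 281 CPM, and the fibronectin gene Fn1 rose from 27.2 ± 2.56 to 563 ± 68.6 CPM. In edgeR's quasi-likelihood test their log2 fold changes were 4.96 (SE 0.227, adjusted p = 7.09e-14), 4.97 (SE 0.219, adjusted p = 4.04e-14) and 4.37 (SE 0.166, adjusted p = 5.21e-15). These genes are annotated on GRCm38 at chromosome 11, 94936224 to 94953042 (Col1a1, ENSMUSG00000001506), chromosome 1, 45311538 to 45349706 (Col3a1, ENSMUSG00000026043) and chromosome 1, 71585520 to 71653200 (Fn1, ENSMUSG00000026193). All 30 tested genes of the matrix and fibrosis list rose, with a median log2 fold change of 3.33 (camera, adjusted p = 1.06e-15; adjusted p = 0.108 with an estimated correlation). The matrix protease gene Mmp14 went from 8.79 ± 1.12 to 128 ± 16.1 CPM. Of 16 myofibroblast and pericyte genes 15 rose, with a median of 2.16 (adjusted p = 1.23e-05; adjusted p = 0.0665 with an estimated correlation). Acta2, the smooth muscle actin of myofibroblasts, rose from 43.8 ± 4.22 to 157 ± 62.8 CPM, beside Vim (log2 2.51) and Pdgfrb (log2 2.22). All 16 genes of TGF-beta signalling rose, with a median of 1.14 (adjusted p = 1.54e-06; adjusted p = 0.0665 with an estimated correlation). Tgfb1 itself rose from 13.1 ± 2.28 to 69.8 ± 7.30 CPM, Tgfbi from 10.99 ± 1.51 to 90.2 ± 14.4 CPM and Ltbp2 from 0.866 ± 0.459 to 41.6 ± 6.31 CPM.

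**Figure D2:**
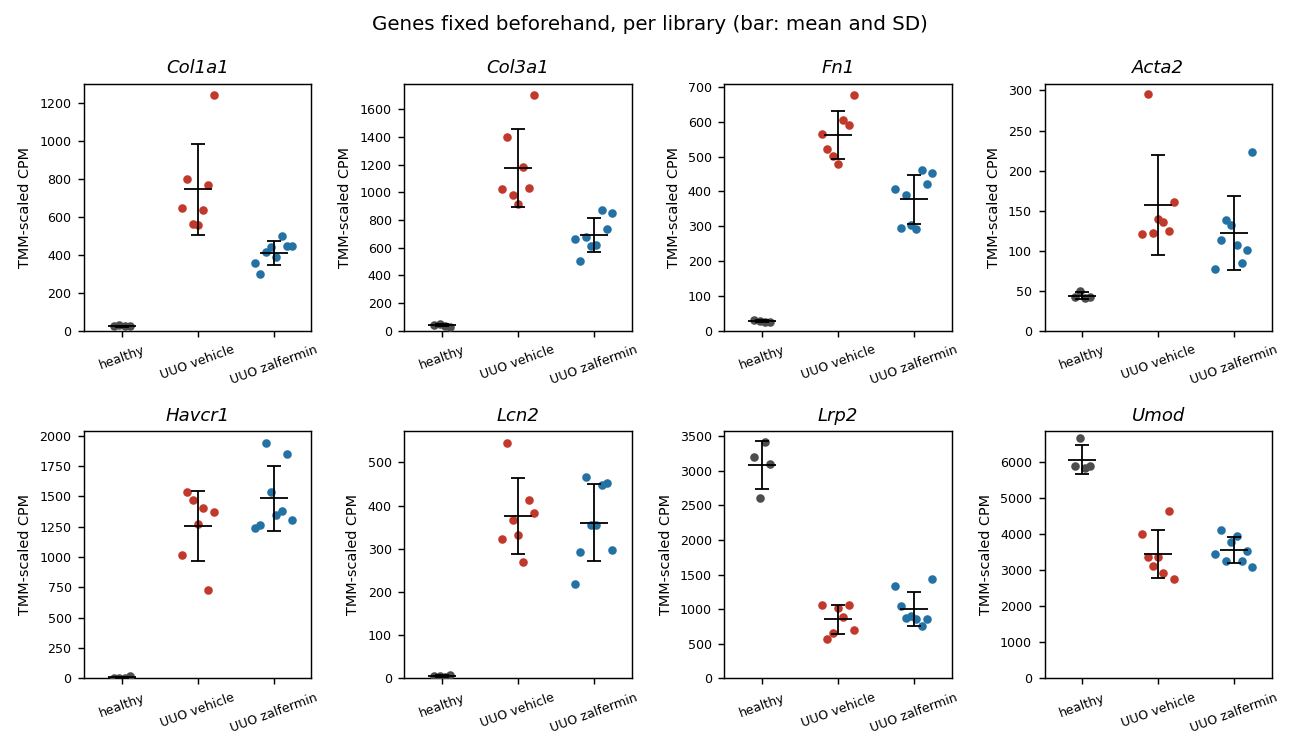
TMM-scaled CPM of 8 genes fixed beforehand; each dot is a library and the black bar is the mean with SD (healthy n = 4, vehicle n = 7, zalfermin n = 8). Col1a1, Col3a1, Fn1, Acta2, Havcr1 and Lcn2 lie above every healthy library in all 15 obstructed libraries, and Lrp2 and Umod lie below.

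Markers of injured tubule rose while markers of the nephron segments fell. Havcr1, the kidney injury molecule gene, rose from 8.27 ± 5.15 to 1255 ± 288 CPM (log2 fold change 7.26, SE 0.336, adjusted p = 8.44e-14). Lcn2, which encodes neutrophil gelatinase-associated lipocalin, rose from 5.22 ± 2.27 to 376 ± 87.8 CPM. Of 18 injured tubule genes 17 rose, with a median log2 fold change of 3.11 (camera, adjusted p = 1.59e-09; adjusted p = 0.0665 with an estimated correlation). Krt20 (log2 8.42) and Vcam1 (log2 5.66) had the smallest p of the list. All 22 proximal tubule genes fell, with a median of -1.88 (adjusted p = 4.95e-11; adjusted p = 0.140 with an estimated correlation). They included the endocytic receptor Lrp2 (3080.1 ± 345 to 851 ± 208 CPM), the glucose transporter Slc5a2 (624 ± 45.9 to 111 ± 14.5 CPM) and Slc3a1 (log2 -1.38). In the thick ascending limb and distal tubule 14 of 16 genes fell, with a median of -1.67 (adjusted p = 4.67e-07; adjusted p = 0.125 with an estimated correlation). Umod, which encodes uromodulin, fell from 6077 ± 394 to 3461 ± 660.4 CPM, and Kcnj1 from 442 ± 26.4 to 125 ± 16.9 CPM. Pvalb had 860 reads in healthy and 2 in vehicle kidneys, a ratio of 759 (95% counting interval 209.5 to 6278). Of 17 collecting duct genes 13 fell, with a median of -1.08 (adjusted p = 0.000113; adjusted p = 0.179 with an estimated correlation). Slc26a4 (log2 -1.63) and Atp6v1g3 (log2 -1.19) were among them. Foxi1, a transcription factor of intercalated cells, rose by a log2 of 0.31 (adjusted p = 0.0406). This call was lost without vehicle replicate 2, 4 or 6 or healthy replicate 2 (adjusted p up to 0.216) and under RLE scaling, DESeq2, voom and the 2-group fit (0.102 to 0.169).

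Podocyte and endothelial lists were not called. Of 12 podocyte genes 3 rose, Ptpro and Synpo among them, and 5 fell, among them Nphs1, Clic3, Col4a3 and Col4a4 (camera, adjusted p = 0.253 for the list). Col4a4 was at 373 ± 43.4 CPM in healthy and 172 ± 25.5 CPM in vehicle kidneys, and Synpo at 66.9 ± 9.73 and 108 ± 8.35 CPM. The Nphs1 call was lost without healthy replicate 4 (adjusted p = 0.0707). Of 14 endothelial genes, Vwf (log2 1.10), Cdh5 (log2 0.99), Pecam1 and Eng rose, and Kdr (log2 -0.59) and Esam fell (adjusted p = 0.713 for the list). The Esam call was lost without vehicle replicate 4 or healthy replicate 1 or 2 (adjusted p up to 0.132), while 4 of the list were called lower without vehicle replicate 1 and 6 higher without healthy replicate 1 or 2. Urothelial keratins Krt14 (0.492 ± 0.523 to 7.94 ± 2.18 CPM) and Krt5 (2.02 ± 0.809 to 18.6 ± 8.75 CPM) rose with Trp63 and Upk1b among 9 urothelial genes (list adjusted p = 0.314). Upk1b was not called without healthy replicate 4 (adjusted p = 0.0753). Where a list had 5 or fewer called members in one direction, those reported here are named, some outside the rule for named genes and after their values were seen.

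Immune genes rose. Adgre1, which encodes the macrophage antigen F4/80, rose from 5.51 ± 1.24 to 71.4 ± 11.03 CPM (log2 fold change 3.70, adjusted p = 1.27e-12). Of 18 macrophage genes 17 rose, with a median of 3.66 (camera, adjusted p = 1.25e-09; adjusted p = 0.0372 with an estimated correlation). Cd14 (log2 3.85) and the lysozyme gene Lyz2 (27.2 ± 4.78 to 451 ± 32.8 CPM) were among them, while Mertk, a receptor for the uptake of dying cells, fell (log2 -0.54). All 15 T and NK cell genes rose, with a median of 1.87 (adjusted p = 0.00135; adjusted p = 0.253 with an estimated correlation), among them Cd4 (log2 3.15) and Lck (log2 2.15). So did all 6 neutrophil genes, Csf3r and Mmp9 included, with a median of 3.28 (adjusted p = 0.00577; adjusted p = 0.153 with an estimated correlation). All 12 genes of dendritic cells and MHC class II rose, with a median of 2.91 (adjusted p = 3.51e-06; adjusted p = 0.179 with an estimated correlation). Cd74 went from 166 ± 23.5 to 1390.3 ± 94.2 CPM and H2-Eb1 from 75.6 ± 13.1 to 591 ± 33.9 CPM. Of 26 genes of cytokines and adhesion 25 rose, with a median of 3.17, unchanged with its 1 member at 0 in healthy kidneys set to its bound (adjusted p = 7.84e-12; adjusted p = 0.0211 with an estimated correlation). The complement gene C3 rose from 21.6 ± 3.12 to 2001 ± 205 CPM and Icam1 from 25.7 ± 1.90 to 154 ± 11.2 CPM. Of 18 interferon response genes 16 rose, with a median of 1.74 (adjusted p = 6.33e-06; adjusted p = 0.168 with an estimated correlation), Oasl2 (log2 2.32) and Irf7 (log2 2.14) included. Rsad2 fell (log2 -0.48), a call lost without healthy replicate 1 or 2 (adjusted p up to 0.0632) and with voom (0.0805). Cd22, Cd79b, Jchain, Igkc and Ighm rose among 7 B and plasma cell genes, a list that was not called (adjusted p = 0.220).

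Genes of oxidative metabolism fell. All 25 genes of oxidative phosphorylation and the TCA cycle fell, with a median log2 fold change of -1.24 (camera, adjusted p = 1.39e-12; adjusted p = 0.168 with an estimated correlation). Sdha fell from 1202 ± 57.6 to 477 ± 43.7 CPM and Ndufs1 by a log2 of -1.57. The 7 tested mitochondrially encoded genes fell too, with a median of -2.06 (adjusted p = 0.000262; adjusted p = 0.245 with an estimated correlation). The level of mt-Cytb went from 28316 ± 1301 to 6807 ± 2078 CPM, with 2540.1 CPM in vehicle replicate 6, and mt-Nd4 fell by a log2 of -2.18. Of 24 genes of fatty acid oxidation and ketogenesis 22 fell, with a median of -1.04 (adjusted p = 3.64e-08; adjusted p = 0.168 with an estimated correlation). Etfa (568 ± 37.8 to 191 ± 23.1 CPM) and Acat1 (log2 -2.18) were among those that fell. Of 17 genes of glycolysis and gluconeogenesis 13 fell, with a median of -0.62 (adjusted p = 0.00247; adjusted p = 0.272 with an estimated correlation). The hexokinase gene Hk2 (0.866 ± 0.476 to 20.6 ± 4.41 CPM) and Pfkp rose. Among 16 antioxidant genes 11 fell, with a median of -0.79 (adjusted p = 0.00657; adjusted p = 0.255 with an estimated correlation), Sod2 (log2 -1.60) and Cat (log2 -1.60) included. Nfe2l2, Hmox1, Slc7a11 and G6pdx rose, the Hmox1 call being lost without vehicle replicate 6 or healthy replicate 1 or 3 (adjusted p up to 0.0700). Sterol and lipid synthesis genes fell in 12 of 18 cases, with a median of -0.55 (adjusted p = 0.000965; adjusted p = 0.260 with an estimated correlation). Cyp51 fell by a log2 of -2.25, to 103 ± 21.6 CPM, and Idi1 by a log2 of -2.33.

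Genes of the cell cycle, of cell death and of the immediate early response rose. Of 20 cell cycle genes 19 rose, with a median of 2.82 (camera, adjusted p = 1.34e-08; adjusted p = 0.140 with an estimated correlation), with Top2a (3.86 ± 1.06 to 41.8 ± 6.21 CPM) and Cdk1 (log2 3.43). Of 16 genes of apoptosis and necroptosis 12 rose, with a median of 1.06 (adjusted p = 0.000403; adjusted p = 0.0665 with an estimated correlation), among them Bak1 (log2 1.62) and Gsdmd (log2 2.22). Of 12 immediate early genes 10 rose, with a median of 1.92 (adjusted p = 0.000674; adjusted p = 0.245 with an estimated correlation), and Junb went from 27.8 ± 7.81 to 154 ± 25.8 CPM. Dusp1 fell (log2 -0.62), a call lost without healthy replicate 4 (adjusted p = 0.0616). Genes of ER stress and ATF4 went both ways and the list was not called (adjusted p = 0.415). Of these 18 genes 9 rose, including Atf3 (log2 4.84) and Asns (5.27 ± 0.908 to 29.8 ± 5.85 CPM), and Shmt2, Hsp90b1, Sesn2 and Herpud1 fell. The Hsp90b1 and Sesn2 calls were lost without healthy replicate 4 (adjusted p = 0.218) and healthy replicate 2 (adjusted p = 0.0643), respectively.

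For the FGF21 axis, Fgfr1 rose from 64.3 ± 5.89 to 88.6 ± 7.10 CPM (log2 fold change 0.46, adjusted p = 2.95e-05) and Fgfr2 rose (log2 0.30), while Fgfr3 fell (log2 -0.78) and Fgfr4 fell (log2 -0.65). The list of 4 tested genes was not called (camera, adjusted p = 0.713). The Fgfr2 call was lost without healthy replicate 2 or 4 (adjusted p up to 0.0875). Fgf21 and Klb, the gene of the co-receptor beta-Klotho, had too few reads for that test. Fgf21 had 0 reads in healthy and 20 in vehicle kidneys, in 6 of 7 libraries (two-sided exact permutation test, p = 0.0455; adjusted over 4 such tests, 0.0909). Klb had 0 and 16 reads, in 5 of 7 libraries (exact p = 0.109; adjusted, 0.145). Genes of FGF receptor and ERK feedback rose in 14 of 18 cases, with a median of 0.90 (adjusted p = 0.00383; adjusted p = 0.168 with an estimated correlation). Fosl1 had 1 read in healthy and 653 in vehicle kidneys, a ratio of 369.9 (95% counting interval 66.2 to 14632). The list's rises included Spred3 (log2 2.22), and Etv1 fell (24.7 ± 3.52 to 8.37 ± 1.89 CPM). In the renin-angiotensin system Ace (365 ± 36.4 to 160.0 ± 54.0 CPM), Enpep, Mme, Atp6ap2 and Agtr1a fell and Agt rose (log2 0.44) among 8 genes (list adjusted p = 0.116; 2 higher without vehicle replicate 2 or 5 or healthy replicate 4). Slc4a1 (log2 -3.00), Alas2 (log2 -1.28), Hba-a1, Hba-a2 and Hbb-bt fell among 6 blood genes, with a median of -1.20 (adjusted p = 0.0248; adjusted p = 0.391 with an estimated correlation). Slc4a1 is also a gene of intercalated cells, and the haemoglobin genes share near-identical reads, so their single values are uncertain. Hba-a1 was not called without healthy replicate 1 or 4 (adjusted p up to 0.0719), and Hba-a2 and Hbb-bt were not called without any 1 of vehicle replicates 1, 2, 3, 4, 5 and 7 and healthy replicates 1 and 4 (adjusted p up to 0.0941 and 0.136), so that 2 blood genes were called without healthy replicate 1. Pnpla2 fell (log2 -0.35) among 10 adipocyte genes (list adjusted p = 0.978; 2 lower without vehicle replicate 6 or healthy replicate 1, and 1 higher without vehicle replicate 6 or healthy replicate 4). Of the 4 tested sex-linked genes 0 were called by edgeR (0 at unadjusted p under 0.05, 0 by DESeq2, 1 by voom; 1 called higher without vehicle replicate 6; list adjusted p = 0.637).

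Among called genes with a symbol other than a provisional one, a mean of at least 5 CPM over all libraries and no overlap between the groups, the largest rises were those of Sprr2f, Krt20 and the chemokine genes Cxcl17, Cxcl2 and Cxcl5. Sprr2f had 0 reads in healthy and 1433 in vehicle kidneys. The ratio was 270.569 with 3 counts over the healthy group as the floor, and 219.759 at the lower end of the 95% counting interval. Cxcl17, Cxcl2 and Cxcl5 had 1, 2 and 1 healthy reads, giving ratios of 490.0 (95% counting interval 87.7 to 19375), 379.5 (105 to 3137) and 417 (74.7 to 16511). These intervals and the floor cover counting error only, and like the ratios they use library totals without TMM factors. The largest falls among the same genes were those of Cyp2d12 (171 ± 18.9 to 4.63 ± 2.53 CPM), Nccrp1 (94.6 ± 40.9 to 3.18 ± 3.23 CPM) and Dnase1 (1121 ± 276 to 49.1 ± 10.7 CPM). They were followed by those of Egf, the epidermal growth factor gene (2404 ± 163 to 113 ± 96.3 CPM), and Kcnt1 (24.0 ± 9.45 to 1.18 ± 0.330 CPM). Cyp2d12 belongs to a family of near-identical genes, and its value is uncertain to that extent.

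In all, edgeR's quasi-likelihood test called 10387 of 16026 genes, 5799 higher and 4588 lower in obstructed kidneys, of which 3145 and 1707 changed at least 2-fold. The median log2 fold change of all tested genes was 0.09 with TMM, 0.01 with RLE and 0.14 with upper-quartile scaling. With a correction for GC content and length between and within groups, chosen after seeing the data, 4383 genes were higher and 6949 lower (38.7% higher, against 55.8% without it), while the correction within groups left 6358 higher and 4891 lower (56.5%). Of 33 tested lists 24 were called, 14 higher and 10 lower. With an estimated correlation 2 held, macrophage and cytokine genes, but neither without vehicle replicate 6 (adjusted p = 0.0883 and 0.0575). Members called when adjusted over the list alone were as many as over all genes except in fatty acid oxidation (2 higher), apoptosis (14 higher), sterol synthesis (13 lower), blood (6 lower) and adipocyte (0) genes.

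**Figure D3:**
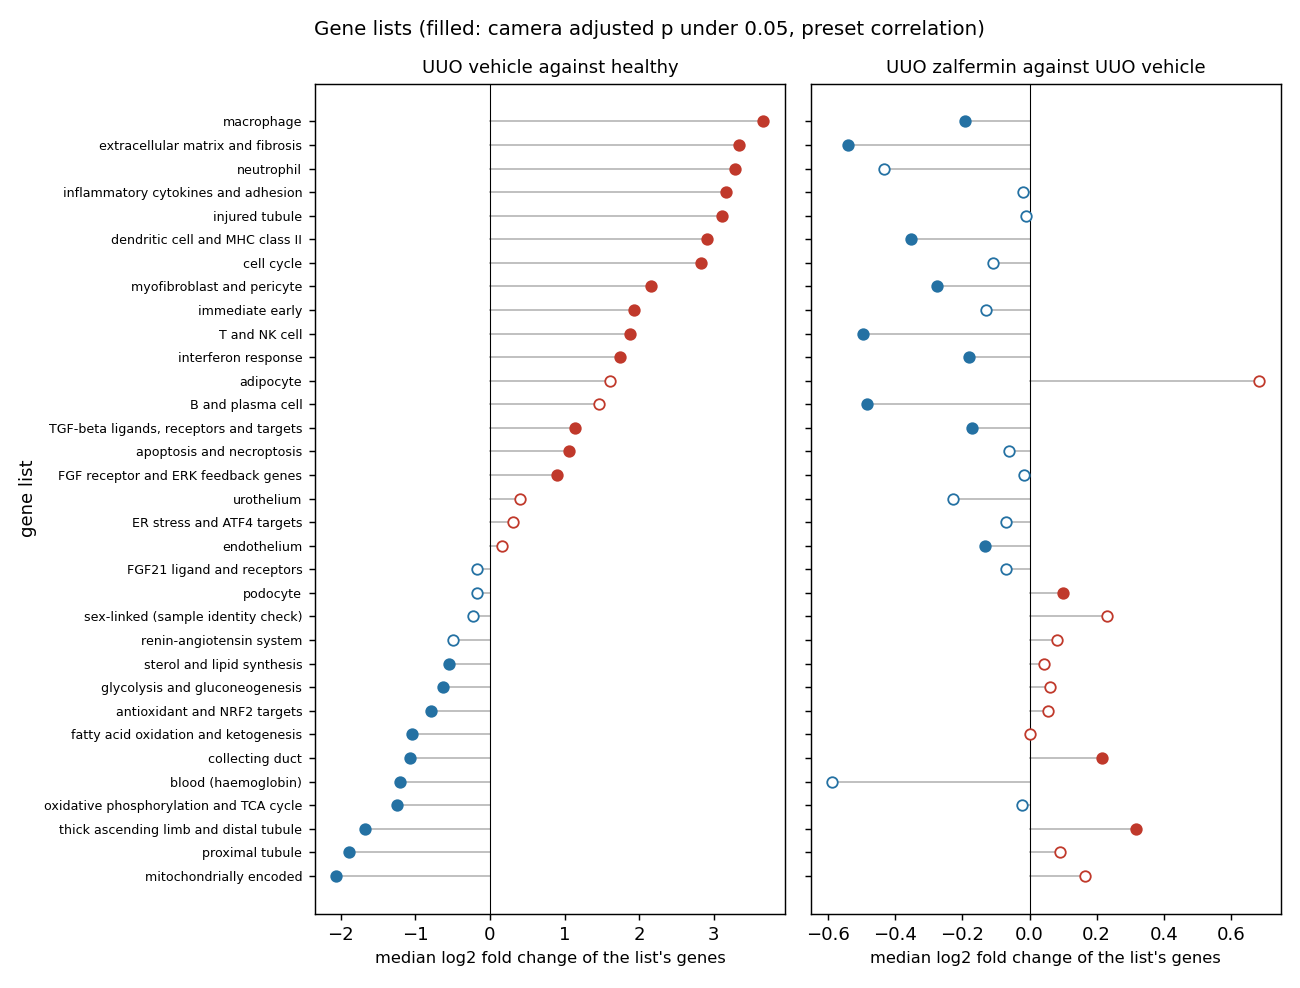
Median log2 fold change of each gene list fixed beforehand, for obstruction (left) and for zalfermin (right); filled circles mark lists called by camera with the preset correlation (24 of 33 and 12 of 33), open circles lists not called. The matrix list had a median of 3.33 with obstruction and -0.54 with zalfermin.

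The second comparison, zalfermin against vehicle in obstructed kidneys, addressed the effect on fibrosis named in the series title. Matrix genes were lower under zalfermin. Col1a1 fell from 746 ± 238 CPM with vehicle (n = 7) to 411 ± 62.3 CPM with zalfermin (n = 8), Col3a1 from 1178 ± 281 to 691 ± 124 CPM, Fn1 from 563 ± 68.6 to 378 ± 70.5 CPM and Col1a2 from 944 ± 169 to 569 ± 71.3 CPM. Their log2 fold changes were -0.86 (SE 0.143, adjusted p = 0.00301), -0.77 (SE 0.138, adjusted p = 0.00543), -0.58 (SE 0.108, adjusted p = 0.00689) and -0.73 (SE 0.110, adjusted p = 0.00122) in edgeR's quasi-likelihood test. All 8 zalfermin libraries lay below the vehicle median for each of the 4 genes. Of 30 matrix genes edgeR called 17 lower and 0 higher, against 22 and 0 at unadjusted p under 0.05, 18 and 0 by DESeq2, 22 and 0 by voom and 21 and 0 when adjusted over the list alone. The list median was -0.54 (camera, adjusted p = 3.09e-22; adjusted p = 0.281 with an estimated correlation; fry, adjusted p = 0.0116). The other members called were Col6a2 (log2 -0.74), Eln, Sparc, Mmp14, Col6a1, Col5a1, Fbn1, Loxl2, Col15a1, Thbs2, Bgn, Mmp2 and Col6a3. The count fell to 11 without vehicle replicate 1 or 2 and to 10 without vehicle replicate 5 or 7 or zalfermin replicate 2, 4 or 5, and it was 19 without vehicle replicate 6.

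Ltbp4 (93.9 ± 13.6 to 70.1 ± 7.36 CPM) and Tgfb3 (14.6 ± 2.24 to 9.28 ± 2.25 CPM) fell among 16 TGF-beta genes (3 lower when adjusted over the list alone). The list median was -0.17 (camera, adjusted p = 0.00434; adjusted p = 0.325 with an estimated correlation). The Ltbp4 call was lost without vehicle replicate 1 or 7 or zalfermin replicate 2 or 5 (adjusted p up to 0.0575), and the Tgfb3 call without vehicle replicate 2, 5 or 7 or zalfermin replicate 1, 2 or 5 (adjusted p up to 0.0711), while 3 members were called without zalfermin replicate 6. Tgfb1 had a log2 fold change of -0.17 (adjusted p = 0.426). The myofibroblast and pericyte list was lower, with a median of -0.28 (adjusted p = 0.000423; adjusted p = 0.325 with an estimated correlation). Of its 16 members 0 were called by edgeR (4 at unadjusted p under 0.05, 3 when adjusted over the list alone, 2 by DESeq2, 2 by voom), and 2 were called lower without zalfermin replicate 3. Pdgfrb had a log2 fold change of -0.35 (adjusted p = 0.0688), Thy1 of -0.54 (adjusted p = 0.0819) and Acta2 of -0.36 (adjusted p = 0.408; 157 ± 62.8 and 122 ± 45.8 CPM).

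The interferon list and 4 immune lists were lower as well. Irf7, a transcription factor of the interferon response, fell from 54.4 ± 3.47 to 39.1 ± 6.70 CPM (log2 -0.48, adjusted p = 0.0139) and Isg15 from 13.8 ± 3.24 to 8.72 ± 1.79 CPM (log2 -0.66, adjusted p = 0.0158). With Oasl2, Bst2 and Oas1a, 5 of 18 interferon response genes fell (5 when adjusted over the list alone), and the list median was -0.18 (camera, adjusted p = 6.00e-06; adjusted p = 0.325 with an estimated correlation). Vehicle replicate 6 had the highest Isg15 level of its group (20.8 CPM) and the lowest mean over the interferon list, and 5 members were called without it (6 without zalfermin replicate 6). Only 3 members were called without any 1 of vehicle replicates 1, 2, 3 and 4 and zalfermin replicates 2, 3, 4, 5, 7 and 8, and 2 without vehicle replicate 7. Oas1a was not called without vehicle replicate 7 (adjusted p = 0.0516). Oasl2 lost its call without any 1 of 12 libraries, all but vehicle replicate 6 and zalfermin replicates 1 and 6 (adjusted p up to 0.0972). Bst2 lost its call without any 1 of 11, all but vehicle replicates 5 and 6 and zalfermin replicates 1 and 6 (adjusted p up to 0.103). H2-Eb1 fell (591 ± 33.9 to 440.4 ± 97.0 CPM, adjusted p = 0.0486) among 12 genes of dendritic cells and MHC class II. That list had a median of -0.35 (adjusted p = 3.46e-05; adjusted p = 0.341 with an estimated correlation; 4 lower when adjusted over the list alone). The H2-Eb1 call was lost without any 1 of 12 libraries, all but vehicle replicates 4 and 6 and zalfermin replicate 6 (adjusted p up to 0.111), and under RLE scaling (0.0504) and without the filter (0.0537). T and NK cell genes had a median of -0.50 (adjusted p = 6.79e-06; adjusted p = 0.325 with an estimated correlation), and B and plasma cell genes of -0.49 (adjusted p = 0.00568; adjusted p = 0.325 with an estimated correlation). Macrophage genes had a median of -0.19 (adjusted p = 0.00403; adjusted p = 0.325 with an estimated correlation). In these 3 lists edgeR and DESeq2 called 0 members each. At unadjusted p under 0.05 there were 7, 4 and 6, all lower except 1 macrophage gene that was higher. Voom called 4, 2 and 1 lower, and edgeR adjusted over the list alone called 0, 4 and 0. Without zalfermin replicate 6 edgeR called 3 T and NK cell genes, 1 macrophage gene and 4 genes of dendritic cells and MHC class II lower. Of the macrophage genes 1 was called lower without zalfermin replicate 4 and 1 higher without vehicle replicate 7. Lyz2 was at 451 ± 32.8 and 353 ± 77.6 CPM (adjusted p = 0.123) and Adgre1 at 71.4 ± 11.03 and 61.6 ± 14.9 CPM (adjusted p = 0.465).

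Among cytokine and adhesion genes, Il1b, which encodes interleukin-1 beta, fell from 9.88 ± 1.63 to 4.88 ± 1.43 CPM (log2 -1.02, adjusted p = 0.00143), and Tnfaip3, an inhibitor of NF-kappaB signalling, rose from 42.0 ± 8.86 to 64.4 ± 9.50 CPM (log2 0.62, adjusted p = 0.00848). The list of 26 was not called (camera, adjusted p = 0.245; 3 higher and 3 lower when adjusted over the list alone), except without zalfermin replicate 7 (adjusted p = 0.0497). Of its members 3 were called lower without zalfermin replicate 6 and 2 higher without zalfermin replicate 8. Neutrophil genes had a median of -0.43 (adjusted p = 0.0953), with adjusted p of 0.0391 and 0.0222 without vehicle replicate 2 or 5. In this list edgeR called 0 of 6 members (0 at unadjusted p under 0.05, by DESeq2 and by voom).

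Of the tubule lists 2 were higher, and so was the podocyte list. Kcnj10 rose from 36.0 ± 5.41 to 48.6 ± 7.95 CPM (adjusted p = 0.0275) among 16 genes of the thick ascending limb and distal tubule. That list had a median of 0.32 (camera, adjusted p = 0.000319; adjusted p = 0.328 with an estimated correlation; 5 higher when adjusted over the list alone). Aqp4, a water channel gene, rose from 12.4 ± 2.55 to 26.5 ± 9.41 CPM (adjusted p = 0.0245) among 17 collecting duct genes, of which 7 were called without vehicle replicate 6. The list median was 0.22 (adjusted p = 4.67e-05; adjusted p = 0.325 with an estimated correlation; 4 higher when adjusted over the list alone). Wt1 rose from 12.2 ± 1.48 to 16.4 ± 2.26 CPM (adjusted p = 0.0268) among 12 podocyte genes. This list had a median of 0.10 (adjusted p = 0.0381; adjusted p = 0.431 with an estimated correlation; 1 higher when adjusted over the list alone). Kcnj10 was not called without vehicle replicate 2, 3 or 7 or zalfermin replicate 1, 2, 3 or 8 (adjusted p up to 0.0736), nor in the 2-group fit (0.0525), while 3 genes of its list were called higher without vehicle replicate 1 or zalfermin replicate 6. Aqp4 was not called without vehicle replicate 2 or 7 or zalfermin replicate 5 (up to 0.0611), and Wt1 without vehicle replicate 2 or 7 or zalfermin replicate 4, 5 or 7 (up to 0.0633). Without vehicle replicate 6, 2 podocyte genes were called. The podocyte list was not called without vehicle replicate 2 (0.190) or 4 (0.0689) or zalfermin replicate 6 (0.0681). Kcnj1 had a log2 fold change of 0.35 (adjusted p = 0.0528), Atp6v0d2 of 0.46 (adjusted p = 0.0526), Nphs1 of 0.29 (adjusted p = 0.164) and Umod of 0.04 (adjusted p = 0.890). Endothelial genes were lower as a list, with a median of -0.13 (adjusted p = 0.0242; adjusted p = 0.660 with an estimated correlation). Of 14 members edgeR called 0 (0 at unadjusted p under 0.05, by DESeq2, by voom and adjusted over the list alone). The list was not called without vehicle replicate 1 (0.119) or zalfermin replicate 5 (0.0667) or 7 (0.0674).

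In the proximal tubule list the amino acid transporter Slc6a19 (52.3 ± 18.4 to 113 ± 38.6 CPM, adjusted p = 0.00689) and Slc5a12 (log2 0.90, adjusted p = 0.0231) rose, and Kap, the kidney androgen-regulated protein gene, fell from 5994 ± 1711 to 3034 ± 1125 CPM (adjusted p = 0.0166). The list of 22 had a median of 0.09 and was not called (camera, adjusted p = 0.119; 8 higher and 3 lower when adjusted over the list alone), except without vehicle replicate 1 (0.0475), 4 (0.0470) or 6 (0.0108) or zalfermin replicate 6 (0.0328). Slc5a12 was not called without vehicle replicate 2 or 7 (adjusted p up to 0.0573), while 4 genes were called higher without vehicle replicate 6 or zalfermin replicate 6, and 2 lower without zalfermin replicate 1. Lrp2 was at 851 ± 208 and 1008 ± 245 CPM (adjusted p = 0.463). Of the 18 injured tubule genes Krt20 rose further, from 56.9 ± 9.28 to 91.7 ± 22.3 CPM (adjusted p = 0.0108; 1 higher when adjusted over the list alone), while Prom1 had a log2 fold change of 0.24 (adjusted p = 0.173), Havcr1 of 0.24 (adjusted p = 0.567) and Lcn2 of -0.06 (adjusted p = 0.893). The list's median was -0.01 and its mean 0.07, the test pointing up, and it was not called (adjusted p = 0.430).

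Among called genes with a symbol other than a provisional one and a mean of at least 5 CPM over all libraries, the largest rises under zalfermin were those of Ugt1a10, a glucuronosyltransferase gene (2.92 ± 0.917 to 12.1 ± 4.57 CPM, log2 2.05, SE 0.262, adjusted p = 0.000634), and the transcription factor Zbtb16 (5.29 ± 1.99 to 17.9 ± 6.71 CPM, adjusted p = 0.00371). They were followed by those of the clock output gene Dbp (19.2 ± 10.8 to 58.5 ± 26.0 CPM, adjusted p = 0.00895), Depp1 (3.40 ± 1.15 to 9.69 ± 5.76 CPM, adjusted p = 0.0168) and the prolactin receptor gene Prlr (13.6 ± 6.29 to 38.6 ± 11.7 CPM, adjusted p = 0.0299). The largest falls among the same genes were those of Pzp (33.8 ± 19.1 to 5.49 ± 4.14 CPM, log2 -2.63, SE 0.363, adjusted p = 0.00111), and Acsm3 (410.4 ± 171 to 115 ± 58.3 CPM, adjusted p = 0.00122). Next were those of the organic anion transporter Slco1a1 (88.2 ± 41.0 to 27.6 ± 13.5 CPM, adjusted p = 0.00663), Sec14l3 (6.20 ± 2.84 to 1.97 ± 1.59 CPM, adjusted p = 0.0301) and Cyp4a12a (19.8 ± 9.43 to 7.87 ± 3.70 CPM, adjusted p = 0.0261). All 8 zalfermin libraries lay beyond the vehicle median for each of these 10 genes, where the naming rule had already required at least 6 of 8. Ugt1a10 (ENSMUSG00000090165, chromosome 1, 88055388 to 88219004) shares exons with the other Ugt1a genes and Cyp4a12a has near-identical copies, so their values are uncertain to that extent. Pzp (ENSMUSG00000030359) lies on chromosome 6, 128483567 to 128526720. Prlr was not called without vehicle replicate 2, 4 or 7 or zalfermin replicate 2, 4, 5 or 8 (adjusted p up to 0.0633) or in the robust fit (0.0540). Sec14l3 was not called without vehicle replicate 1 or 2 or zalfermin replicate 4, 5 or 7 (up to 0.0620) or in the 2-group fit (0.0544). Cyp4a12a lost its call without vehicle replicate 2 or 4 or zalfermin replicate 2, 4, 5 or 7 (up to 0.0625).

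**Figure D4:**
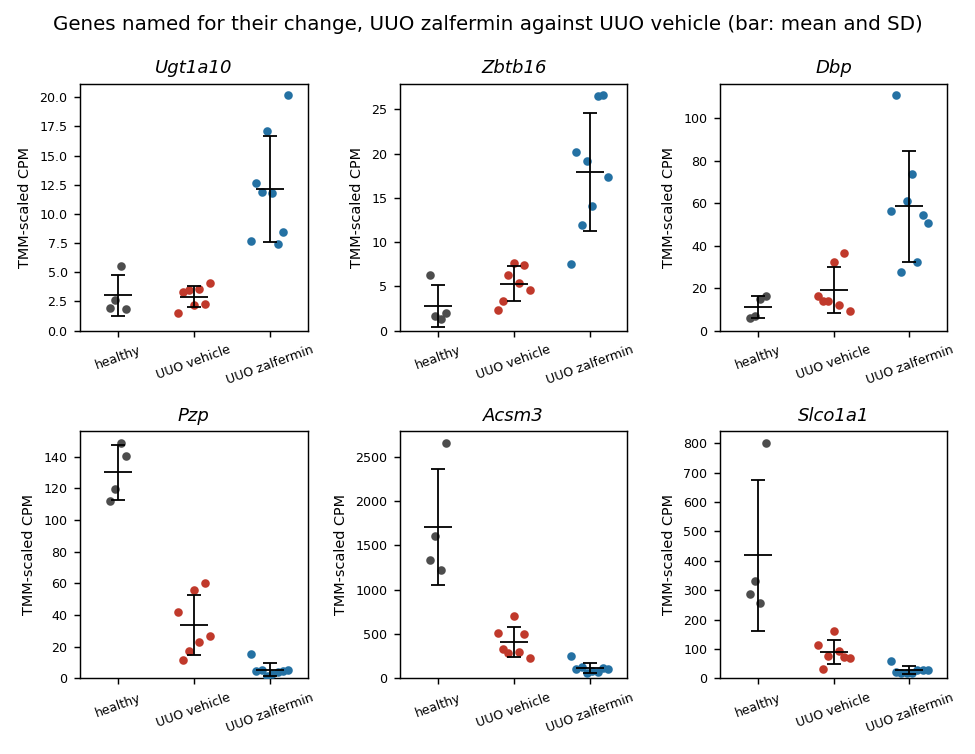
TMM-scaled CPM of 6 of the genes named for the largest changes under zalfermin at 5 CPM or more; each dot is a library and the black bar is the mean with SD (healthy n = 4, vehicle n = 7, zalfermin n = 8). Pzp, Acsm3 and Slco1a1 are highest in healthy, lower in vehicle and lowest in zalfermin kidneys.

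Metabolic and growth lists were not called. Fatty acid oxidation genes had a median of 0.00 (camera, adjusted p = 0.761) and 0 of 24 were called by edgeR (8 at unadjusted p under 0.05, 2 higher and 2 lower when adjusted over the list alone, 3 by DESeq2 and 1 by voom), though 1 was called higher without vehicle replicate 1 or 6 or zalfermin replicate 6. Ppargc1a was at a log2 of 0.41 (adjusted p = 0.0692) and Acadm at -0.50 (adjusted p = 0.1002). Oxidative phosphorylation genes had a median of -0.02 and a mean of 0.02 (adjusted p = 0.398), the test pointing up, with 0 of 25 called by edgeR (1 at unadjusted p under 0.05, 0 by DESeq2, by voom and adjusted over the list alone). Mitochondrially encoded genes had a median of 0.17 (adjusted p = 0.106), with 0 of 7 called by edgeR (0 at unadjusted p under 0.05, by DESeq2, by voom and adjusted over the list alone). Slc2a2 rose (103 ± 20.9 to 147 ± 19.2 CPM, adjusted p = 0.0212; not called without vehicle replicate 2, 0.0521) among 17 glycolysis and gluconeogenesis genes (list adjusted p = 0.364; 1 higher when adjusted over the list alone). Vehicle replicate 6 had the highest mean of its group over the glycolysis list and the lowest over the mitochondrially encoded list. Without it the oxidative phosphorylation and glycolysis lists were called higher (adjusted p = 0.00255 and 0.00209), but neither passed with an estimated correlation (adjusted p = 0.718 and 0.301). The mitochondrially encoded list was called without vehicle replicate 1 (0.0475) or 4 (0.0330). Cell cycle genes had a median of -0.11 (adjusted p = 0.0904), with 0 of 20 called by edgeR (1 at unadjusted p under 0.05, 0 by DESeq2, by voom and adjusted over the list alone). The cell cycle list was called without vehicle replicate 1 (0.00324) or 7 (0.0381) or zalfermin replicate 1 (0.0215), 5 (0.0251) or 8 (0.0359). These calls used the preset correlation. With all libraries an estimated correlation gave camera's adjusted p = 0.702 for the cell cycle list and for the mitochondrially encoded list.

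Gpx3, which encodes an extracellular glutathione peroxidase, rose from 6837 ± 1275 to 9967 ± 1750.4 CPM (adjusted p = 0.0314) among 16 antioxidant genes (list adjusted p = 0.2003; 1 higher when adjusted over the list alone). Its call was lost without vehicle replicate 1, 3, 4, 5 or 7 or zalfermin replicate 2, 3, 5 or 8 (adjusted p up to 0.0816). Creb3l1 (log2 -0.77, adjusted p = 0.0147) and Atf3 (43.4 ± 8.27 to 31.3 ± 5.57 CPM, adjusted p = 0.0474) fell among 18 genes of ER stress and ATF4 (list adjusted p = 0.115; 1 higher and 5 lower when adjusted over the list alone). This list was called without vehicle replicate 3 (0.0318) or 5 (0.0222), with 3 members called lower without vehicle replicate 3 or 6 and 1 higher without vehicle replicate 4 or 6. Fosb (6.87 ± 7.77 to 1.90 ± 0.636 CPM, adjusted p = 0.0311) fell with Atf3 among 12 immediate early genes (list adjusted p = 0.115; 1 higher and 3 lower when adjusted over the list alone; 1 called higher without zalfermin replicate 3). Atf3 was not called without vehicle replicate 1, 2, 4 or 5 or zalfermin replicate 2, 3, 4, 5, 7 or 8 (adjusted p up to 0.109). Fosb was not called without vehicle replicate 1 or 3 or zalfermin replicate 1, 2, 3, 4, 5 or 8 (up to 0.0830), and neither in the 2-group fit (0.0544 and 0.0550). Ace, the angiotensin-converting enzyme gene, fell from 160.0 ± 54.0 to 94.5 ± 22.3 CPM (adjusted p = 0.0203), in the same list of 8 as before (adjusted p = 0.473; 3 higher and 1 lower when adjusted over the list alone; 1 called higher without vehicle replicate 6).

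Of the receptor genes, Fgfr1 had a log2 fold change of -0.04 (adjusted p = 0.809), Fgfr2 of 0.26 (adjusted p = 0.132) and Fgfr3 of -0.26 (adjusted p = 0.290). The FGF21 list (camera, adjusted p = 0.704) and the list of FGF receptor and ERK feedback genes (adjusted p = 0.794) each had 0 members called by edgeR (2 and 2 at unadjusted p under 0.05, 0 and 1 by DESeq2, 0 and 0 by voom, 1 and 1 adjusted over the list alone). Etv1 was at a log2 of 0.45 (adjusted p = 0.0770) and Phlda1 at -0.46 (adjusted p = 0.132). Fgf21 had 20 reads in 6 of 7 vehicle libraries and 2 reads in 2 of 8 zalfermin libraries (two-sided exact permutation test, p = 0.00637; adjusted over 4 such tests, 0.0255). That result did not pass without vehicle replicate 2, 4, 6 or 7 or zalfermin replicate 2, 3, 4, 5, 6, 7 or 8 (adjusted, 0.0513 to 0.0816). Klb had 16 and 10 reads (exact p = 0.340; adjusted, 0.340).

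The remaining lists were not called and edgeR called 0 of their members: apoptosis (camera, adjusted p = 0.372), blood (0.372), urothelium (0.430) and sex-linked genes (0.0940), each with 0 members at unadjusted p under 0.05, by DESeq2, by voom and adjusted over the list alone. The same held for sterol synthesis (0.928; median 0.04, mean -0.01, the test pointing down; 3 members at unadjusted p under 0.05, 0 by DESeq2 and by voom, 1 lower without zalfermin replicate 8) and for adipocyte genes (0.372; median 0.68; 3 at unadjusted p under 0.05, 0 by DESeq2 and 1 by voom), with 0 adjusted over the list alone in both. The sex-linked list was called without the filter (0.0308) and without vehicle replicate 5 (0.0222). Vehicle replicate 6, kept in both of these fits, had the lowest Ddx3y level of its group (14.9 CPM). Among adipocyte genes, Retn was at 0.558 ± 0.671 CPM with vehicle and 4.06 ± 5.01 CPM with zalfermin (adjusted p = 0.125), and Plin1 at 0.681 ± 0.909 and 2.92 ± 3.16 CPM (adjusted p = 0.261).

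In all, edgeR's quasi-likelihood test called 290 genes, 139 higher and 151 lower under zalfermin (47.9% higher), 25 and 23 of them at least 2-fold, and 2479 genes had an unadjusted p under 0.05. With upper-quartile scaling 105 were higher and 191 lower (35.5% higher), and with corrections for GC content and length chosen after seeing the data 358 and 211 (62.9% higher, between and within groups) or 388 and 256 (60.2%, within groups). The count was 179 without vehicle replicate 2, 517 without vehicle replicate 6 (276 of the 290 among them), 157 without vehicle replicate 7 and 153, 162 and 155 without zalfermin replicate 2, 4 and 5. DESeq2 called 602 and voom 1148. Of the 33 lists 12 were called, 3 higher and 9 lower, and 0 held with an estimated correlation (smallest adjusted p = 0.281).

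The third comparison asked what still differed from healthy kidneys under zalfermin. Col1a1 was at 411 ± 62.3 CPM with zalfermin and 24.0 ± 2.67 CPM in healthy kidneys (log2 fold change 4.10, adjusted p = 5.79e-13), and Col3a1 at 691 ± 124 and 37.6 ± 7.75 CPM (log2 4.20). Fn1 was at 378 ± 70.5 and 27.2 ± 2.56 CPM (log2 3.80) and Acta2 at 122 ± 45.8 and 43.8 ± 4.22 CPM (log2 1.48). Havcr1 (log2 7.49), Lcn2 (log2 6.12), Adgre1 (log2 3.48), Tgfb1 (log2 2.24) and Fgfr1 (log2 0.42) were also higher, and Lrp2 (log2 -1.61) and Umod (log2 -0.77) lower, than in healthy kidneys. All 11 of these genes passed edgeR's quasi-likelihood test, and for each of them the 8 zalfermin libraries lay outside the range of the 4 healthy ones. The test called 10298 genes, 5976 higher and 4322 lower; with the correction for GC content and length between and within groups, chosen after seeing the data, 39.5% of 11089 were higher, and with the correction within groups 58.1% of 11092, against 58.0% here. The median log2 fold change of all genes was 0.13 with TMM, 0.03 with RLE and 0.14 with upper-quartile scaling.

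The last comparison asked which genes changed by obstruction moved back under zalfermin. Acnat2 went from 76.7 ± 13.8 CPM in healthy to 32.9 ± 4.59 in vehicle and 55.7 ± 5.96 in zalfermin kidneys, the clock repressor Nr1d1 from 82.4 ± 22.9 to 35.4 ± 5.71 and 65.8 ± 11.1 CPM, and Cyp2d26 from 167 ± 6.62 to 14.3 ± 3.95 and 37.1 ± 14.4. Acss1, an acetyl-CoA synthetase gene, went from 359.7 ± 21.98 to 63.9 ± 11.1 and 108 ± 18.9 CPM. In the other direction the matrix gene Dpt, which encodes dermatopontin, went from 2.29 ± 0.848 to 18.1 ± 3.66 and 9.05 ± 1.71 CPM. Acnat2 (log2 -0.46), Cyp2d26 (log2 -2.16), Acss1 (log2 -1.73) and Dpt (log2 1.97) still differed from healthy kidneys. Nr1d1 did not pass (log2 -0.33, adjusted p = 0.0643), although it did under RLE scaling (0.0177), DESeq2 (0.0150), voom (0.00670), the 2-group fit (0.0259) and without zalfermin replicate 2 (0.0376) or 8 (0.0460) or healthy replicate 4 (0.0268). Other genes went the same way in both comparisons: Pzp (130.3 ± 17.3, 33.8 ± 19.1 and 5.49 ± 4.14 CPM), Acsm3 (1706 ± 652, 410.4 ± 171 and 115 ± 58.3) and Slco1a1 (419 ± 257, 88.2 ± 41.0 and 27.6 ± 13.5) fell in both. Bhlhe41 (2.16 ± 0.171, 4.19 ± 0.914 and 8.77 ± 1.82 CPM) and Abcc4 (log2 0.90 and 0.64) rose in both.

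Of the 290 genes called under zalfermin, 214 had changed in the opposite direction with obstruction, 42 in the same direction and 34 were not called with obstruction. Among the 214, 127 had risen with obstruction and 87 had fallen. Of the 214, 173 still differed from healthy kidneys. Independent lists of these sizes would share 94.4 genes with opposite and 93.5 with the same signs. The vehicle libraries enter both comparisons, which by itself gives opposite signs. Over 20 simulations of unchanged zalfermin libraries the overlap with opposite signs was 0. With a mean of 0.05 genes called under zalfermin it could hardly be larger, so it is no baseline for the 214. The covariance of the log2 fold changes averaged -0.0183 (-0.0253 to -0.0133) there, against -0.112 observed, a difference of -0.0940. Simulated genes varied independently, so deviations that many genes share, as in vehicle replicate 6, were left out. The simulated range may therefore be too narrow. With the vehicle libraries split between the comparisons in 70 ways, the mean overlap was 82.7 genes with opposite signs (0 to 680) and 35.1 with the same sign (0 to 468), beside 46.1 and 45.8 for independent lists, and the covariance averaged -0.0856 (-0.169 to 0.0081). The count of 214 became 133, 404 and 103 without vehicle replicate 2, 6 and 7, and 112, 126 and 111 without zalfermin replicate 2, 4 and 5.

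**Figure D5:**
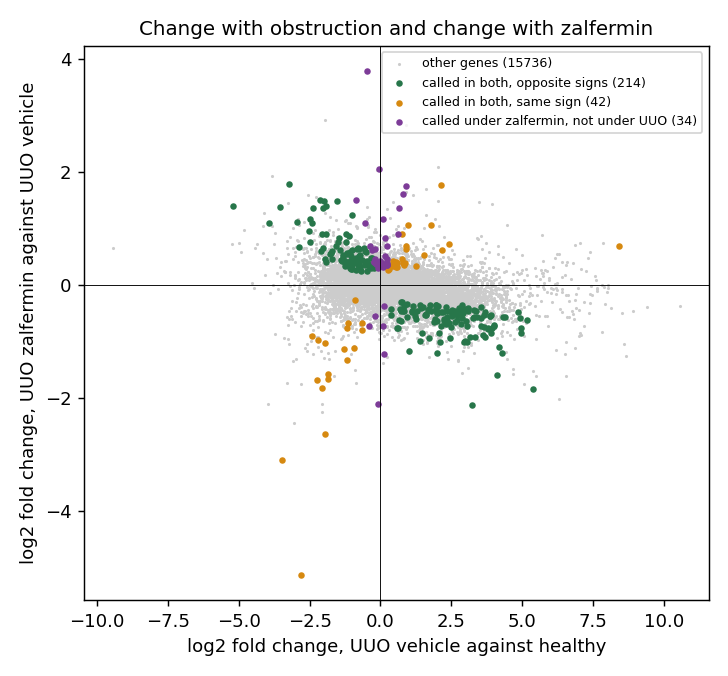
Each point is a gene, placed by its log2 fold change with obstruction (x axis) and with zalfermin (y axis). Coloured points are the 214 genes called in both with opposite signs, the 42 called in both with the same sign and the 34 called under zalfermin alone, and grey points are the other 15736 genes.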

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

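The tests of GC content and length for vehicle replicate 6 were set before their result was seen, though their division into part and whole was made afterwards; those of its depth and of milder injury, and the splits of the libraries, were chosen after. A library was taken to stand apart when its gap to the nearest other library of its group was large for the group's range (Dixon's criterion). Of 408 groups of values 47 had such a library, and 15 of the 47 were in vehicle replicate 6. For independent, normally distributed values chance gives about 1 in 20, or 20.4. Many of these values were CPM of single genes, some with few reads, and related measures were counted repeatedly, so 20.4 is only a rough guide.

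Vehicle replicate 6 differed from the other vehicle libraries in several gene groups at once. It had 19788 genes detected (21374 to 22216 in the others), a mean Spearman correlation across genes with its group of 0.958 (0.983 to 0.986) and a mitochondrially encoded share of 1.10% (3.09% to 4.21%), with mt-Nd4 at 1025 CPM (2238 to 3052) and mt-Cytb at 2540.1 CPM (6513 to 9249.8). The mean log2 CPM over lists was high for glycolysis (8.17 against 7.46 to 7.75), the FGF21 receptors (5.74 against 5.35 to 5.43) and blood (5.88 against 2.999 to 3.94), with Fgfr4 at 54.8 CPM (31.3 to 38.2). It was low for interferon response (4.43 against 4.88 to 5.11), sex-linked (4.07 against 5.47 to 5.85) and mitochondrially encoded genes (9.53 against 11.14 to 11.64), with Ddx3y at 14.9 CPM (54.7 to 78.0) and the tubule gene Prom1 at 152 CPM (190.04 to 207). Isg15, an interferon gene, was in contrast high there, at 20.8 CPM (11.2 to 13.8).

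In this library 2426 genes lay at least 2-fold from the mean of the other vehicle libraries, 1939 below and 487 above. GC content and transcript length took 0.437 of the variance of its gene deviations, against at most 0.225 in the other vehicle libraries, so such a bias may be part of the cause. A smooth trend in GC content and length was not the whole cause. After each library's trend was removed, the correlation of vehicle replicate 6 with its group still stood apart (Dixon ratio 0.823, against 0.906 before). The gap itself narrowed: its correlation went from 0.958 to 0.979, and that of the nearest other, vehicle replicate 2, from 0.983 to 0.988. A bias of another form would not be removed in this way and stays open. Lower depth is argued against by its total of 13.998 M counts (M, mega), because libraries with fewer counts had more genes detected. Milder injury stays open: its deviations correlated across genes with the difference between healthy and vehicle kidneys (0.219), but its mitochondrially encoded share of 1.10% lay farther from healthy kidneys, and haemoglobin genes took 0.0561% of its counts (at most 0.0109% in the others).

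Among matrix and myofibroblast genes, Col1a1 was high in vehicle replicate 7 (1244 CPM, 560.03 to 799 in the others), Acta2 in vehicle replicate 2 (296 CPM, 120.4 to 161) and in zalfermin replicate 8 (223 CPM, 76.7 to 138), and Col6a2 in zalfermin replicate 6 (80.9 CPM, 45.5 to 57.7). The podocyte list was low in vehicle replicate 2 (mean log2 CPM 4.94, 5.21 to 5.33 in the others). Among immune genes, zalfermin replicate 6 had high H2-Eb1 (661 CPM, 360.1 to 457) and Cd74 (1585 CPM, 849 to 1115), and zalfermin replicate 7 high Il1b (8.26 CPM, 3.91 to 5.16). In healthy replicate 2 H2-Eb1 (95.0 CPM, 66.99 to 71.3) and Ms4a7 (2.40 CPM, 1.096 to 1.28) were high.

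Tubule and metabolic genes stood apart in other libraries. Vehicle replicate 1 had high Slc6a19 (89.2 CPM, 37.4 to 59.7), Cyp2d12 (9.75 CPM, 1.59 to 4.83) and Cyp2d26 (22.8 CPM, 11.07 to 14.3) and low Top2a (29.4 CPM, 40.7 to 49.1). Zalfermin replicate 1 was high for Pzp (15.2 CPM, 1.60 to 5.48), Acsm3 (250.5 CPM, 64.01 to 127) and Slco1a1 (58.9 CPM, 16.6 to 28.96). In zalfermin replicate 8 Nccrp1 (18.96 CPM, 0.753 to 4.89) and Dnase1 (90.9 CPM, 33.6 to 60.7) were high, in zalfermin replicate 7 Sprr2f (32.98 CPM, 3.27 to 12.3) and in zalfermin replicate 2 Klf9 (275 CPM, 196 to 225). Healthy replicate 4 had high Slco1a1 (801 CPM, 255 to 331), Cyp4a12a (84.1 CPM, 26.7 to 35.1) and Havcr1 (15.9 CPM, 4.71 to 6.49) and low Shmt1 (73.6 CPM, 87.1 to 88.4). Healthy replicate 2 had high Umod (6667 CPM, 5844 to 5909) and low Foxi1 (17.9 CPM, 26.7 to 28.1) and Slc5a12 (208 CPM, 277 to 289.7), and healthy replicate 1 high Zbtb16 (6.32 CPM, 1.26 to 1.96). The only reads of these genes in healthy kidneys, 1, 2 and 1, made Cxcl17 in healthy replicate 2 (0.0888 CPM), Cxcl2 in healthy replicate 4 (0.196 CPM) and Cxcl5 in healthy replicate 1 (0.0890 CPM) the only healthy libraries above 0.

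Random assignment of the libraries to groups is argued against as the source of the counts of called genes. The splits cannot tell treatment from another difference between the groups, such as time of collection. In 100 splits of the libraries per comparison, the real one included, only 1, the real split, called as many: 10387 genes for obstruction (highest other 5624), 290 for zalfermin against vehicle (highest other 15) and 10298 for zalfermin against healthy (highest other 4042).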

How the results depend on the processing

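The corrections for GC content and length were chosen after the results were seen and were run only on the counts of called genes; the other alternatives were planned, and no gene or list result reversed under those. With the correction within groups obstruction kept its balance (6358 higher and 4891 lower), and zalfermin had 388 higher and 256 lower. With the correction between and within groups the balance turned, to 4383 higher and 6949 lower with obstruction (5799 and 4588 without it) and to 358 and 211 under zalfermin (139 and 151). The balance also moved with the scaling and tool. With obstruction 55.8% of called genes were higher with TMM, 50.5% with RLE, 50.8% with DESeq2 and 59.2% with upper-quartile scaling. For zalfermin against healthy these shares were 58.0%, 51.4%, 51.6% and 59.2%.

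The tallies of genes here cover those taken by the naming rule. For obstruction, of 829 comparisons of such a gene with another scaling, tool, filter or fit 823 stayed on the same side of the threshold, 5 fell below it (4 of Foxi1, 1 of Rsad2) and 1 passed it, and of 1142 with a library left out 1134, 7 and 1. Among genes named outside the rule Hba-a2 and Hbb-bt fell below in 8 of 11 fits each, and Esam and Hmox1 in 3. The count of 10387 genes was 9447 to 11410 under the other scalings, tools, filters and fits, and 9789 to 11199 with a library left out (11199 without vehicle replicate 6). For zalfermin against healthy 164 of 168 and 249 of 252 gene comparisons stayed, and 4 and 3 passed the threshold. All 363 list tests for obstruction with a library left out stayed.

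Zalfermin against vehicle depended more on the processing. Of 741 gene comparisons 713 stayed, 7 fell below and 21 passed, and of 1395 with a library left out 1293, 83 and 19. Outside the rule Oasl2 fell below in 12 of 15 fits, Bst2 and Per3 in 11 and Fkbp5 in 9. The 290 genes became 602 with DESeq2 and 1148 with voom, 153 (without zalfermin replicate 2) to 517 (without vehicle replicate 6) with a library left out, and 569 and 644 with the corrections for GC content and length between and within groups and within groups. The 214 genes moved back became 449 with DESeq2, 886 with voom, and 432 and 433 with these corrections. With a library left out they became 103 (without vehicle replicate 7) to 404 (without vehicle replicate 6). They were 82.7 on average with the vehicle libraries split between the comparisons. The split leaves fewer libraries in each comparison and also removes the sharing of libraries, and these were not told apart. For the other changes the cause was not tested.

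The 24 lists called with obstruction became 2 with an estimated correlation, macrophage and cytokine genes, and the 12 under zalfermin became 0, while fry called 29 with obstruction and 1 under zalfermin, the matrix list. Camera's settings differed here in the correlation between the genes of a list. The preset was 0.01, while the estimates ran from 0.0405 (renin-angiotensin system) to 0.971 (mitochondrially encoded genes), with 0.468 for the matrix list. The fall in called lists under camera came with these higher correlations. The adjusted p with the preset hold only where genes are correlated that weakly. Why fry differed was not tested. With a library left out, 470 of 495 list tests under zalfermin stayed, 6 fell below and 19 passed, all with the preset correlation.

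At 12209122 to 14844103 counts per library, Fgf21 and Klb had at most 20 reads in a group, too few for the quasi-likelihood test.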

Other observations

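The 8 gene lists in this part, the clock and male-biased patterns and all their tests were chosen after the results were seen. The lists hold genes whose change had prompted them, so no test of a list is given as evidence that its change is real, and the counts and medians only describe it.

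Of 17 genes of glucuronidation and xenobiotic metabolism 7, Ugt1a10 among them, were called higher under zalfermin, with a median log2 fold change of 0.31 over the list. Of 14 genes of glycine, serine and proline catabolism, Shmt1 (log2 0.38), Gldc (0.95), Glul (0.58) and Prodh2 (0.60) were higher, with a median of 0.20. Of 11 amino acid transporters of the proximal tubule Slc6a19, Slc7a7 (0.53) and Slc7a9 (0.42) were higher, with a median of 0.19. Without vehicle replicate 6 edgeR called 7, 5 and 3 of them higher. With obstruction 13 of 17, 13 of 14 and 10 of 11 of these genes had been called lower, against 4588 of all 16026 tested genes. The same vehicle libraries enter both comparisons, and some genes prompted the lists by rising against them. These counts are therefore no evidence of a reversal.

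Clock genes shifted under zalfermin: of 11 genes of the Dbp phase Dbp, Nr1d1, Nr1d2, Per3 and Bhlhe41 were higher (median 0.87; 7 called without vehicle replicate 6), and of 5 of the Arntl phase Arntl (-1.11) and Nfil3 (-0.72) were lower (median -0.72; 2 called without it). Per3 lost its call without any 1 of 11 libraries, all but vehicle replicates 4 and 6 and zalfermin replicates 3 and 6 (adjusted p up to 0.120), and Nr1d2 without vehicle replicate 2 or 7 or zalfermin replicate 2 (up to 0.0521). Vehicle replicate 6 is argued against as the source, since the phases stayed apart without it (difference of medians 1.67; quartiles 0.684 to 0.981 and -0.785 to -0.0536). Another time of day of collection in the zalfermin group, not given in the sources used here, could separate the phases as seen (difference of medians 1.59), and so could higher glucocorticoid signalling, whose genes outside the clock lists had a median of 0.44 (11 genes). These cannot be told apart, because collection times are not known and the glucocorticoid genes also follow the time of day.

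Of the 12 glucocorticoid-responsive genes Fkbp5 (log2 0.70), Klf9 (0.45) and Zbtb16 were called higher, and 7 without vehicle replicate 6. Fkbp5 lost its call without vehicle replicate 1, 2, 3, 5 or 7 or zalfermin replicate 2, 4, 5 or 7 (adjusted p up to 0.0939), and Klf9 without vehicle replicate 2 or 7 (up to 0.0511).

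Male-biased kidney genes were lower under zalfermin: of 11 Acsm3, Kap, Slco1a1 and Cyp4a12a were called (5 without vehicle replicate 6), with a median of -0.98 (quartiles -1.19 to -0.38). Cyp4a12a lost its call without vehicle replicate 2 or 4 or zalfermin replicate 2, 4, 5 or 7 (adjusted p up to 0.0625). A smaller share of proximal tubule cells as a whole is argued against by the 20 proximal tubule genes outside the list, whose median was 0.094 (quartiles -0.01 to 0.39). A loss confined to part of the proximal tubule was not tested. A continued fall of genes lowered by obstruction is argued against by the other genes it lowered at least 2-fold. With the vehicle libraries split so that the comparisons shared none, their median was 0.0353 on average (-0.106 to 0.188), and no split had a lower quartile below -0.356. Vehicle replicate 6 is argued against by the list's median of -1.02 without it (quartiles -1.22 to -0.253). Lower androgen or growth hormone signalling may be the source and was not tested here. Of 4 female-biased genes Prlr was called higher, a call lost without vehicle replicate 2, 4 or 7 or zalfermin replicate 2, 4, 5 or 8 (adjusted p up to 0.0633).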
